A study of Canis lupus familiaris with 10 samples.

How the data were processed

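Expression was measured on GeneChip Canine Gene 1.0 ST arrays in Mock and BLT2 lines of MDCK cells at 5 steps of a calcium switch, 10 arrays in all with 1 per line and step. Each RNA was mixed from 3 preparations, per the labels' protocols, so preparations were averaged before hybridisation and no replicate arrays exist. The deposited values are log2 signals, as read from their range, which starts at 1.55. The submitters' processing notes name Affymetrix Expression Console and GCRMA, a method that corrects probe background by sequence and scales arrays to a shared distribution. Their versions were not given in the sources used here. Because the authors made 1 normalized signal table, differences that act on all probe sets of an array cannot be seen in it, and low signals carry little information on change.

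The table held 32391 probe sets. In the platform annotation, 16545 had 1 gene symbol, 370 had several and named no gene here, and 15476 were not listed with a symbol. These gave 15947 genes, 516 of them with several probe sets, for which the probe set with the highest mean was used. Symbols are those of the annotation and can be old. A gene was kept when its signal lay above the median of all values, 7.21, on at least 2 arrays, which left 10498 genes. No further normalization was applied. Columns were matched to samples by their names, and 0 columns were left without a sample.

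Step comparisons and the difference between the lines were tested in limma 3.58.1 under R 4.3.3 with an additive model of line and step over all 10 arrays. This leaves 4 residual degrees of freedom, moderated by eBayes with a prior of 3.46. The error is the part of the line-by-step table that the additive model does not explain, so it holds both array noise and true differences in response between the lines. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons, with a threshold of 0.05. The response to 12-HHT within a line compares 1 array with 1 array and is given by size alone, for genes whose higher signal lay above 7.21. Choices of test, filter, lists and rule for naming genes were made before the data were examined, except where a setting is said to have been added later.

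The analysis used 26 gene lists with 682 members, repeats counted, of which 618 were paired with a probe set. They covered tight junctions, adherens junctions and desmosomes, immediate early genes, ERK pathway output, YAP and TEAD targets, the unfolded protein response, the ATF4 amino acid response, cholesterol synthesis, DNA replication and mitosis. Further lists held epithelial mesenchymal transition, integrins and matrix receptors, actin cytoskeleton and SRF, NF-kB and inflammation, interferon stimulated genes, the eicosanoid pathway, calcium handling, hypoxia and glycolysis, heat shock, and NRF2 and metallothionein. The last were p53 targets, kidney tubule transport, keratins and epithelial identity, and markers of fibroblasts, endothelium and leukocytes. Lists share some genes. Lists with at least 5 tested genes were tested with limma camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list. For each line alone, a list's median was set among 10000 random lists of the same size matched on mean signal, as a description of the arrays.

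The text names, for each fitted comparison, up to 10 genes at each end among those called with the same direction in both lines and a log2 change of at least 1. To these come up to 4 called genes of each list, by size, and the genes LTB4R2, LTB4R, CLDN1, CLDN2, CLDN4, CLDN7, OCLN, TJP1 and CDH1 whatever their value. For BLT2 against Mock the direction had to hold at all 5 steps. For 12-HHT by line the rule took genes that differed at least 2-fold in 1 line and by at least 0.58 from the other line. Where fewer than 5 genes passed, the largest fitted changes of at least 0.5 in both lines are given as values. Only part of the genes under this rule is printed.

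The fits were tested on simulated arrays with the real means and spreads of the 10498 genes. For 18 h against 0 h, 68% of genes planted at ±1 and 98% at ±2 were recovered, with 12 of 10298 unchanged genes called. For BLT2 against Mock these were 94%, 99% and 11, and for the difference between lines on calcium return 54%, 92% and 6. A list raised by 0.5 at 18 h was recovered as higher, and 0 of 23 unchanged lists were called. Noise was drawn independently for each gene and these lists were random. The simulation therefore does not measure false calls among genes or lists that vary together, such as mitosis, with an estimated correlation of 0.859.

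Alternatives were no signal filter, a stricter one (75th percentile, 6362 genes), quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, and an intensity trend in eBayes. Others were only the 4 arrays of a comparison, no 12-HHT arrays, no step term, and leaving out each array in turn. Cyclic loess, the test of calcium return between lines (also without each step), the list tests without each array and 3 more gene lists were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.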

Results

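Transcript levels were measured in MDCK cells, an epithelial line from dog kidney that forms sealed sheets, while calcium was taken away and given back. One line carried human BLT2, a cell surface receptor for the lipid 12-hydroxyheptadecatrienoic acid (12-HHT), and a Mock line did not. Each line was sampled at 5 steps of the calcium switch, a protocol in which removing calcium opens the junctions between cells and restoring it lets them form again. These steps were the confluent culture in medium with 10% serum (0 h), 2 h and 18 h in calcium-free medium, 2 h of calcium return after the 18 h, and the same return with 200 nM 12-HHT. The series title names the question as the part that 12-HHT and BLT2 play in expression after this switch. Each of the 10 line-by-step combinations had 1 GeneChip array, hybridised with RNA mixed from 3 preparations. Log2 signals started at 1.55, array medians lay between 7.16 and 7.27, and 10498 genes passed the signal filter. The mean correlation of an array with the other arrays was 0.975 for the BLT2 array at 2 h and 0.982 to 0.987 for the rest. The first 3 principal components held 35.0%, 29.9% and 13.6% of the variance. LTB4R2, which encodes BLT2, and its relative LTB4R were named by no probe set in the annotation used, so their levels were not analysed here. With 1 array per combination, limma p-values of single genes rest on the spread left by an additive fit of line and step. The number of arrays limits their precision. Camera p-values instead compare the genes of a list with the other genes. The later test of calcium return between the lines takes its error from the BLT2 minus Mock differences across steps. Changes given ± SE are log2 values from the additive fit, except in that later test. Each step rests on 2 arrays, 1 per line.

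After 2 h without calcium, PPP1R15A, a phosphatase subunit that restarts translation after stress, rose by 2.88 ± 0.16 (limma adjusted p = 0.00123), and CHAC1, which degrades glutathione, rose by 2.71 ± 0.17. The stress transcription factor ATF3 rose by 2.21 ± 0.14, the zinc exporter SLC30A1 by 2.17 ± 0.20, and the cystine transporter SLC7A11 by 1.79 ± 0.15. The matrix protein gene CCN1 gained 1.38 ± 0.09, XBP1, a factor of the unfolded protein response, gained 1.15 ± 0.09, and DDIT4, an inhibitor of mTOR signalling, also rose (adjusted p = 0.00216). The metallothionein MT1E, which binds zinc and copper, rose by 4.27 ± 0.42, with 4.45 in Mock and 4.09 in BLT2 cells. Lower transcripts included CDC25A, a phosphatase that drives cell cycle entry, which fell by 1.71 ± 0.18. Both lines moved the same way for each of these genes, which the rule for naming the largest changes required here and in the step comparisons below. The first 8 held their call in every fit that left out 1 array, while MT1E had an adjusted p of 0.0517 without the BLT2 2 h array and CDC25A 0.0565 without the BLT2 0 h array.

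Grouped by lists, 12 of 25 tested genes of the ATF4 amino acid response rose and 0 fell over all genes, against 21 and 0 adjusted over the list alone (limma camera adjusted p = 1.43e-18). The immediate early list had 15 of 31 genes higher and 1 lower, or 22 and 1 adjusted over the list alone (adjusted p = 4.31e-17). Targets of YAP and TEAD, the effectors of Hippo signalling, had 8 of 18 higher, or 11 adjusted over the list alone (adjusted p = 7.55e-10), among them CCN1 and LATS2, the latter at 1.31 ± 0.14. LATS2 was not called without the Mock 0 h or the BLT2 2 h array, with an adjusted p of up to 0.0606. With an estimated correlation between genes these 3 lists were still called, at adjusted p = 0.0138, 0.0421 and 0.0421 with an estimated correlation. The other 9 lists called here were lost with it. ERK pathway output had 4 of 21 higher and 1 lower, 5 and 1 adjusted over the list alone (adjusted p = 0.000211, and adjusted p = 0.301 with an estimated correlation). NF-kB and inflammation had 3 of 19 higher, 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.000249, and adjusted p = 0.548 with an estimated correlation). In the NRF2 and metallothionein list 4 of 16 rose, over all genes and adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.215 with an estimated correlation). Those 4 were MT1E, MT2A, SLC30A1 and SLC7A11, which bind or carry metals and cystine. The p53 target list had 3 of 20 higher by both counts, SESN2, BTG2 and DDB2, the last a DNA repair factor (adjusted p = 0.0380, and adjusted p = 0.616 with an estimated correlation). SESN2 is also a member of the ATF4 list and BTG2 of the immediate early list. Kidney tubule transport had 1 of 18 higher, KCNJ16, and 4 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.446 with an estimated correlation). Adherens junctions and desmosomes had 1 of 23 higher by both counts, NECTIN2 (adjusted p = 0.0454, and adjusted p = 0.679 with an estimated correlation). Lower as groups were mitosis, with 1 of 29 called (adjusted p = 0.00105, and adjusted p = 0.741 with an estimated correlation), and DNA replication, with 1 of 32 (adjusted p = 0.0164, and adjusted p = 0.788 with an estimated correlation). Cholesterol synthesis was lower too, with 1 of 19 (adjusted p = 0.0305, and adjusted p = 0.741 with an estimated correlation). In those 3 lists 1 gene each also fell adjusted over the list alone. Leaving out the Mock 2 h array ended the calls of mitosis (0.281), DNA replication (0.341), cholesterol synthesis (0.115), adherens junctions (0.153) and NRF2 and metallothionein (0.113), values in brackets being adjusted p. Without the BLT2 0 h array the direction of DNA replication turned (0.666) and mitosis (0.393), adherens junctions (0.285) and kidney tubule transport (0.111) were lost. Without the BLT2 2 h array p53 targets (0.483), kidney tubule transport (0.202) and cholesterol synthesis (0.0729) were lost, and without the Mock 0 h array cholesterol synthesis (0.136) and p53 targets (0.0847). Adherens junctions were also lost without either array of calcium return alone (0.0530) or with 12-HHT (0.0521). Quantile normalization ended the calls of adherens junctions (0.0598) and p53 targets (0.0792), as did the absence of a signal filter (0.119 and 0.0854). MT2A, SESN2, DDB2 and KCNJ16 were not called without the Mock 0 h, BLT2 0 h or BLT2 2 h array (up to 0.219), nor BTG2 without the Mock 0 h or BLT2 2 h array (up to 0.0588). NECTIN2 was called only with all arrays or without the Mock 2 h or an 18 h array (up to 0.280 in the other fits). The BLT2 2 h array, on which these groups partly rest, was the array least correlated with the others, at 0.975.

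In all, 485 of 10498 genes passed at 2 h, 277 higher and 208 lower, and 109 of them moved at least 2-fold, 95 up and 14 down. The count was 49 without the Mock 0 h array (44 higher and 5 lower), 34 without the BLT2 0 h array (34 and 0), 1024 without the Mock 2 h array (302 and 722) and 68 without the BLT2 2 h array (62 and 6). It was 200 without either 18 h array, and 298 without either 12-HHT array. Of the 52 genes named for this step, 8 stayed called without each array in turn, and 40 lost the call without the BLT2 0 h array.

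After 18 h without calcium, MT1E was up by 3.75 ± 0.42 and GAPT, an adaptor of immune cell signalling, by 3.71 ± 0.39 (limma adjusted p = 0.00221 and 0.00207). CHN1, a GTPase-activating protein for Rac, rose by 2.86 ± 0.15 (adjusted p = 0.000616), PPP1R15A by 2.82 ± 0.16, and the p53 targets TP53INP1 and SESN2 by 2.58 ± 0.32 and 2.53 ± 0.28. IFI44L, an interferon stimulated gene, fell by 3.71 ± 0.55 (adjusted p = 0.00418), the histone gene H2BC11 by 3.31 ± 0.27, FGFBP1, a carrier of fibroblast growth factors, by 2.85 ± 0.35, and the secreted factor NDNF by 2.28 ± 0.24. These 10 genes moved the same way in both lines and stayed called without each array in turn.

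Among junction genes the changes went both ways. CLDN16, a tight junction protein that passes magnesium and calcium, fell by 2.01 ± 0.27 (limma adjusted p = 0.00332), while PARD6B, a polarity protein, rose by 0.72 ± 0.10. CLDN4, a sealing claudin, rose by 1.00 ± 0.23 (adjusted p = 0.0184). It was not called without the Mock 0 h, Mock 18 h, BLT2 0 h or BLT2 18 h array, with values of 0.81 to 1.20 and an adjusted p of up to 0.120. TJP1, the scaffold ZO-1, rose by 0.56 ± 0.10 and was not called without the Mock 0 h or the BLT2 18 h array (adjusted p of up to 0.0789). CDH1, which encodes E-cadherin, rose by 0.53 ± 0.10 and was not called without the Mock 0 h, Mock 18 h or BLT2 0 h array (up to 0.0727). CLDN2, a pore-forming claudin, was -2.45 in Mock and -0.27 in BLT2 cells (adjusted p = 0.111). The BLT2 signals behind the latter value lay below the filter level, so it carries little information. CLDN7 was at -0.31 ± 0.12 (adjusted p = 0.0987), CLDN1 at 0.06 ± 0.15 (0.826) and OCLN, which encodes occludin, at -0.03 ± 0.14 (0.904). Of 35 tight junction genes 7 rose and 3 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.934), with a median of 0.03 and a mean of -0.04. Adherens junctions and desmosomes had 5 of 23 higher and 1 lower by both counts (adjusted p = 0.734).

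Other groups moved more as a whole at 18 h. Of 25 genes of the ATF4 amino acid response, 20 rose and 1 fell, or 23 and 2 adjusted over the list alone (camera adjusted p = 1.41e-08, and adjusted p = 0.0610 with an estimated correlation). Of 18 interferon stimulated genes 13 fell by both counts (adjusted p = 1.86e-07, and adjusted p = 0.562 with an estimated correlation), with medians of -1.02 in Mock and -1.09 in BLT2 cells. Of 19 cholesterol synthesis genes 14 fell, 15 adjusted over the list alone (adjusted p = 1.02e-06, and adjusted p = 0.562 with an estimated correlation). FDFT1, which encodes squalene synthase, fell by 1.84 ± 0.33 but was not called without the Mock 0 h or the BLT2 18 h array (adjusted p of up to 0.0668). DNA replication had 17 of 32 lower, 19 adjusted over the list alone (adjusted p = 3.70e-07, and adjusted p = 0.588 with an estimated correlation), among them the ribonucleotide reductase subunit RRM2 at -1.14 ± 0.12 and the helicase subunit MCM7 at -1.07 ± 0.13. Mitosis had 10 of 29 lower, 12 adjusted over the list alone (adjusted p = 7.88e-06, and adjusted p = 0.588 with an estimated correlation), among them CDC20 at -0.99 ± 0.14. YAP and TEAD targets had 11 of 18 higher, 14 adjusted over the list alone (adjusted p = 2.51e-05, and adjusted p = 0.176 with an estimated correlation). The immediate early list had 15 of 31 higher and 2 lower, 17 and 2 adjusted over the list alone (adjusted p = 6.59e-05, and adjusted p = 0.428 with an estimated correlation), led after PPP1R15A by the phosphatase DUSP1 at 2.03 ± 0.16. The unfolded protein response had 10 of 22 higher, 13 adjusted over the list alone (adjusted p = 0.000271, and adjusted p = 0.588 with an estimated correlation), among them the chaperone DNAJB9 at 1.69 ± 0.26. Of 20 p53 targets 11 rose, 13 adjusted over the list alone (adjusted p = 0.000620, and adjusted p = 0.562 with an estimated correlation). The cell cycle inhibitor CDKN1A gained 2.29 ± 0.37 and was not called without the BLT2 18 h array (adjusted p of 0.0582). NF-kB and inflammation had 9 of 19 higher and 1 lower by both counts (adjusted p = 0.00247, and adjusted p = 0.588 with an estimated correlation), and the call was lost without the Mock 18 h array (0.128). ERK pathway output had 10 of 21 higher and 1 lower by both counts (adjusted p = 0.00275, and adjusted p = 0.562 with an estimated correlation).

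The lists without a call at 18 h also held single genes that moved. Integrins and matrix receptors had 5 of 22 higher and 2 lower (camera adjusted p = 0.277), with the laminin chain LAMB3 at 1.46 ± 0.13. The heat shock list had 3 of 16 higher and 4 lower, 4 and 6 adjusted over the list alone (adjusted p = 0.411), with the chaperone HSPH1 at -1.64 ± 0.18. NRF2 and metallothionein had 3 of 16 higher and 2 lower (adjusted p = 0.934), with a median of -0.02 and a mean of 0.27. Hypoxia and glycolysis had 3 of 26 higher and 5 lower (adjusted p = 0.177), and the epithelial mesenchymal transition list had 1 of 11 higher and 3 lower (adjusted p = 0.483). In the eicosanoid pathway 2 of 14 rose and 3 fell (adjusted p = 0.420), in calcium handling 2 of 19 rose (adjusted p = 0.934), and in the actin cytoskeleton and SRF list 2 of 18 rose and 2 fell (adjusted p = 0.934). Kidney tubule transport had 1 of 18 higher and 4 lower, 2 and 5 adjusted over the list alone (adjusted p = 0.230), and keratins and epithelial identity 4 of 20 higher and 1 lower (adjusted p = 0.946). Where no second count is given, the numbers adjusted over the list alone were the same. Markers of other cell types were mostly below the filter. Of the endothelial markers 5 were tested and 1 rose, FLT1 at 0.38 ± 0.10 (limma adjusted p = 0.0326), a call lost without the Mock 0 h, Mock 18 h, BLT2 0 h or BLT2 18 h array (adjusted p of up to 0.229), and that list was not called (0.734). The fibroblast list kept 3 genes and the leukocyte list 4, too few for the list test, with medians of -0.16 for both and 0 genes called in limma (median change only, no list test).

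At 18 h 2860 of 10498 genes passed, 1579 higher and 1281 lower, and 426 moved at least 2-fold, 220 up and 206 down. The count was 890 without the Mock 0 h array, 953 without the BLT2 0 h array, 1168 without the Mock 18 h array and 591 without the BLT2 18 h array. Of the 101 genes named, 45 stayed called without each array, and 53 lost the call without the BLT2 18 h array. Medium and serum changed together with calcium at this step and at 2 h, so their effects cannot be told apart.

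When calcium was returned for 2 h, PPP1R15A fell by 2.77 ± 0.16 against 18 h (limma adjusted p = 0.00141) and CCN1 by 1.95 ± 0.09 (adjusted p = 0.000621), in both lines and in every fit that left out 1 array. Other falls were AMOTL2, an angiomotin family member that binds YAP, at -1.72 ± 0.16, and the stress gene GADD45B at -1.79 ± 0.20. The carbonic anhydrase CA12 rose by 1.39 ± 0.13, the transporter ABCC5 by 1.54 ± 0.16, TIPARP, a target of the aryl hydrocarbon receptor, by 1.25 ± 0.13, and HMOX1, which encodes heme oxygenase, by 1.19 ± 0.13. These 6 genes moved the same way in both lines but none was called without the Mock 18 h or the BLT2 18 h array, with an adjusted p of up to 0.161. HMOX1 and TIPARP were also lost without the Mock calcium return array. Among the claudins and partners always followed, none passed: CLDN4 was at -0.18 ± 0.23 (adjusted p = 0.695), CLDN7 at 0.28 ± 0.12 (0.265), CLDN2 at 0.22 ± 0.56 (0.853), CLDN1 at 0.05 ± 0.15 (0.888), OCLN at 0.05 ± 0.14 (0.875), TJP1 at -0.10 ± 0.10 (0.623) and CDH1 at 0.07 ± 0.10 (0.731).

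In the list tests of calcium return 12 lists were called, and 0 with an estimated correlation. YAP and TEAD targets had 7 of 18 lower, 9 adjusted over the list alone (camera adjusted p = 1.82e-06, and adjusted p = 0.0964 with an estimated correlation). The ATF4 amino acid response had 5 of 25 lower, 1 higher and 9 lower adjusted over the list alone (adjusted p = 2.42e-05, and adjusted p = 0.0964 with an estimated correlation), and the immediate early list 2 of 31 higher and 8 lower, 4 and 12 adjusted over the list alone (adjusted p = 0.000785, and adjusted p = 0.300 with an estimated correlation). Mitosis was lower with 1 of 29 called by both counts (adjusted p = 0.00213, and adjusted p = 0.686 with an estimated correlation), and not called without the BLT2 calcium return array (0.595). Higher were cholesterol synthesis (adjusted p = 0.000722, and adjusted p = 0.609 with an estimated correlation) and interferon stimulated genes (adjusted p = 0.0145, and adjusted p = 0.686 with an estimated correlation), with 0 of 19 and 0 of 18 members called in limma by either count. Their medians split by line. Cholesterol synthesis was at 0.04 in Mock and 0.84 in BLT2 cells, the latter at percentile 100 among 10000 random lists of like expression, and interferon stimulated genes were at -0.17 and 0.46. Both calls were lost without the BLT2 18 h array (0.106 and 0.819), and that of interferon genes also without the BLT2 calcium return array (0.471). Kidney tubule transport had 1 of 18 higher by both counts, the transcription factor PAX8 at 0.93 ± 0.12 (adjusted p = 0.000722, and adjusted p = 0.254 with an estimated correlation). PAX8 was not called without any 1 of the 4 arrays of these steps (adjusted p of up to 0.167). Adherens junctions and desmosomes were higher with 0 of 23 members called (adjusted p = 0.00213, and adjusted p = 0.605 with an estimated correlation), and integrins and matrix receptors with 1 of 22 (adjusted p = 0.00213, and adjusted p = 0.605 with an estimated correlation). NRF2 and metallothionein had 2 of 16 higher, HMOX1 and the glutathione synthesis subunit GCLM, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00393, and adjusted p = 0.216 with an estimated correlation). The epithelial mesenchymal transition list (adjusted p = 0.00718, and adjusted p = 0.254 with an estimated correlation) and the actin cytoskeleton and SRF list (adjusted p = 0.0245, and adjusted p = 0.642 with an estimated correlation) were higher with 0 of 11 and 0 of 18 members called by either count. The actin call was lost without the BLT2 calcium return array (0.184), and without a signal filter (0.0965), as was that of the transition list (0.0763). Tight junction genes were not called as a list (adjusted p = 0.228), with 1 of 35 lower, PARD6B at -0.84 ± 0.10, which was not called without any 1 of the same 4 arrays (up to 0.167). GCLM was not called in 8 of the 10 fits without 1 array (up to 0.360).

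At calcium return 351 of 10498 genes passed in limma, 81 higher and 270 lower, of which 16 rose and 63 fell at least 2-fold, against 2009 at an unadjusted p under 0.05. The count was 5 without the Mock 18 h array (CCN1, PPP1R15A, EIF1B, FGFBP1 and IDO1), 2 without the BLT2 18 h array (CCN1 and PPP1R15A), 17 without the Mock and 68 without the BLT2 calcium return array. It was 156 without either 0 h array, and 228 without either 12-HHT array. FGFBP1 and IDO1 were chosen after their values were seen. Medium was changed together with calcium at this step, so their effects cannot be told apart, here or against the starting culture below.

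Against the starting culture, in cells with calcium back for 2 h, CHN1 stood 2.60 ± 0.15 higher (limma adjusted p = 0.000626), PLAT, tissue plasminogen activator, 2.19 ± 0.13, the NF-kB target BIRC3 2.14 ± 0.23 and LAMB3 1.63 ± 0.13. H2BC11 was at -3.13 ± 0.27, the histone genes H1-1 and H2AC6 were at -2.01 ± 0.10 and -1.90 ± 0.11, and CCN1 at -1.24 ± 0.09. These 8 genes moved the same way in both lines and were the only ones of 84 named that stayed called without each array, while 76 lost the call without the BLT2 0 h array. CLDN16 was at -1.48 ± 0.27 (adjusted p = 0.0153), CLDN4 at 0.82 ± 0.23 (0.0526), TJP1 at 0.46 ± 0.10 (0.0224) and CDH1 at 0.60 ± 0.10 (0.0102), all but CLDN4 called. CLDN16 and CDH1 lost the call without the Mock 0 h, BLT2 0 h or BLT2 calcium return array (up to 0.1301), and TJP1 without any 1 of the 4 arrays of these steps (up to 0.153). For CLDN1 the change was 0.10 ± 0.15, for CLDN2 -1.13 ± 0.56, for CLDN7 -0.03 ± 0.12 and for OCLN 0.02 ± 0.14, and none of these 4 passed (adjusted p of 0.210 or more). The CLDN2 value joins unlike lines. From 18 h to calcium return CLDN2 moved by -0.005 in Mock and 0.45 in BLT2 cells, after the unlike changes at 18 h given above. DNA replication had 15 of 32 lower and mitosis 14 of 29, 25 and 24 adjusted over the list alone (camera adjusted p = 4.40e-12 for both, and adjusted p = 0.498 with an estimated correlation for both). Interferon stimulated genes had 8 of 18 lower, 12 adjusted over the list alone (adjusted p = 6.83e-07, and adjusted p = 0.498 with an estimated correlation), and cholesterol synthesis 2 of 19 lower, 0 adjusted over the list alone (adjusted p = 0.000455, and adjusted p = 0.616 with an estimated correlation). Higher were NF-kB and inflammation with 6 of 19, 7 adjusted over the list alone (adjusted p = 2.20e-05, and adjusted p = 0.498 with an estimated correlation), and the ATF4 amino acid response with 9 of 25, 15 adjusted over the list alone (adjusted p = 3.45e-05, and adjusted p = 0.197 with an estimated correlation). Among p53 targets 9 of 20 were higher by both counts (adjusted p = 0.000179, and adjusted p = 0.498 with an estimated correlation), and among integrins and matrix receptors 5 of 22, 9 adjusted over the list alone (adjusted p = 0.000220, and adjusted p = 0.498 with an estimated correlation). The unfolded protein response had 3 of 22 higher by both counts (adjusted p = 0.00267, and adjusted p = 0.616 with an estimated correlation), and NRF2 and metallothionein 3 of 16, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.00505, and adjusted p = 0.360 with an estimated correlation). Adherens junctions and desmosomes had 7 of 23 higher and 1 lower, 7 and 2 adjusted over the list alone (adjusted p = 0.00554, and adjusted p = 0.600 with an estimated correlation), a call lost without the BLT2 calcium return array (0.05003). ERK pathway output had 3 of 21 higher by both counts (adjusted p = 0.0201, and adjusted p = 0.498 with an estimated correlation), a call lost without the Mock 0 h array (0.0528). Tight junctions had 1 of 35 higher and 1 lower (adjusted p = 0.281).

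This comparison called 1579 of 10498 genes, 814 higher and 765 lower, and 104 and 134 of them by at least 2-fold. The count was 404 without the Mock 0 h array, 40 without the BLT2 0 h array, 487 without the Mock and 615 without the BLT2 calcium return array. It was 1031 without either 18 h array.

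Genes chosen in 1 line and read in the other gave a measure of recovery in which choice and reading share no array. The 220 genes at least 2-fold up at 18 h in Mock cells had a median in BLT2 cells of 1.18 at 18 h and 0.72 after calcium return. The 235 genes down in Mock cells read -1.19 and -0.55 in BLT2 cells. In the other direction, the 264 genes up in BLT2 cells read 1.10 and 0.71 in Mock cells, and the 258 genes down in BLT2 cells read -1.09 and -1.01. Genes up at 2 h in Mock cells, 113 in number, read 1.22 at 2 h, 0.92 at 18 h and 0.34 after calcium return in BLT2 cells, and the 127 genes up at 2 h in BLT2 cells read 1.12, 0.78 and 0.25 in Mock cells. The 10 genes down at 2 h in Mock cells read -1.29, -0.59 and 0.29 in BLT2 cells, while the 101 genes down at 2 h in BLT2 cells read -0.50, -0.40 and -0.52 in Mock cells. No test applies to these medians.

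**Figure D1:**
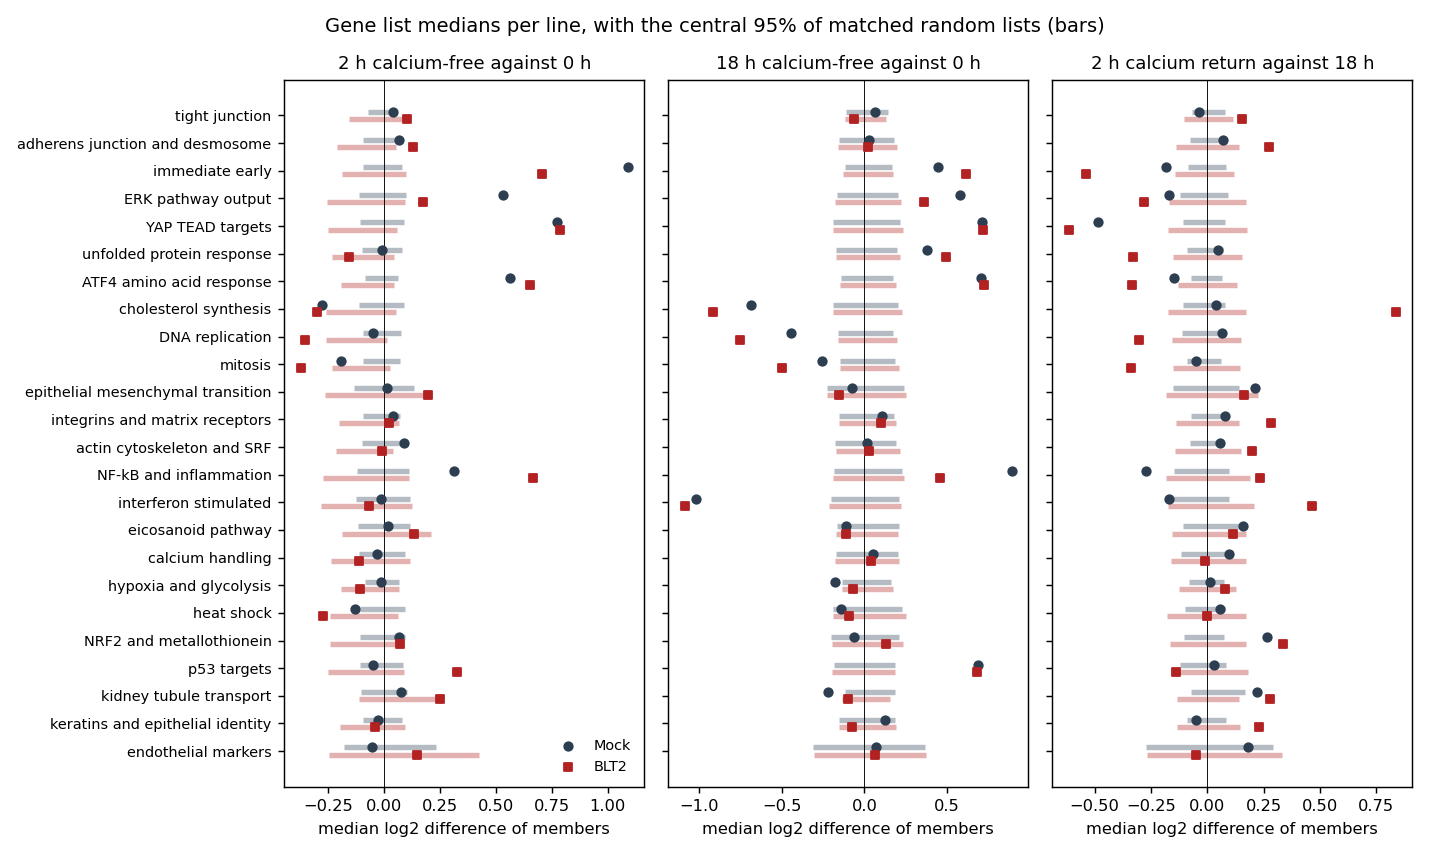
Median log2 change of 24 gene lists in Mock and BLT2 cells for 2 h against 0 h, 18 h against 0 h and calcium return against 18 h, with bars for the central 95% of random lists of like expression. Interferon stimulated genes sit at -1.02 and -1.09 at 18 h, and on calcium return at -0.17 in Mock and 0.46 in BLT2 cells.

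With 12-HHT during calcium return, 6 genes differed at least 2-fold from calcium return alone in BLT2 cells and 0 in Mock cells. These values have no replicate and no test. In BLT2 cells ANKRD1, a YAP target of the muscle ankyrin family, was higher by 1.62 on the log2 scale (3.08-fold), EREG, a ligand of the EGF receptor, by 1.27, FST, which encodes the activin antagonist follistatin, by 1.10, and PTGS2, the prostaglandin synthase COX-2, by 1.02. Lower were the protease ADAMTS1 at -1.28 and the transcription factor EGR1 at -1.15. The same genes in Mock cells were at -0.13, 0.33, 0.14, -0.04, -0.14 and -0.09. CLDN4 was higher by 0.50 in BLT2 cells (1.41-fold), at percentile 99.5 of the genes of that pair of arrays, and differed by 0.00 in Mock cells, at percentile 43.5. CLDN1 was at 0.10 in Mock and -0.14 in BLT2 cells, CLDN2 at -0.10 and -0.33, CLDN7 at -0.03 and 0.02, OCLN at 0.04 and 0.05, TJP1 at 0.01 and -0.05, and CDH1 at -0.002 and -0.02. The BLT2 signals of CLDN2, 6.95 without and 6.62 with 12-HHT, also lay below the filter level.

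Over both lines together, CCN1 had the largest value with at least 0.5 in each line, 0.61 in Mock and 0.54 in BLT2 cells, and did not pass (limma adjusted p = 1). In the list test 3 of the lists were higher with 12-HHT, with 0 members called in limma over all genes. The immediate early list had a median of 0.13 over 31 genes, 1 called adjusted over the list alone (camera adjusted p = 1.97e-07, and adjusted p = 0.277 with an estimated correlation). YAP and TEAD targets had a median of 0.11 over 18 genes, 1 called adjusted over the list alone (adjusted p = 2.92e-08, and adjusted p = 0.124 with an estimated correlation). ERK pathway output had a median of 0.11 over 21 genes, 0 called adjusted over the list alone (adjusted p = 0.000120, and adjusted p = 0.443 with an estimated correlation). By line, the immediate early median was 0.05 in Mock and 0.17 in BLT2 cells, that of ERK output 0.05 and 0.18, and that of YAP targets 0.05 and 0.17. Percentiles among random lists were 94.7, 90.2 and 90.2 in Mock and 100 in BLT2 cells for all 3. Without the BLT2 array of calcium return alone these calls were lost, at 0.393 for the immediate early list, 0.484 for YAP targets and 0.443 for ERK output, and the last was lost without the BLT2 12-HHT array too (0.0921). NF-kB and inflammation had medians of -0.01 in Mock and 0.06 in BLT2 cells, and tight junctions of 0.01 and 0.00, neither list called (adjusted p of 0.358 and 0.828). Lists called numbered 3 with all arrays, 8 without the Mock calcium return array, 13 without the Mock 12-HHT array, 5 without the BLT2 calcium return array and 12 without the BLT2 12-HHT array.

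In the fit of both lines 0 of 10498 genes passed for 12-HHT in limma, with 29 at an unadjusted p under 0.05 where 524.9 would be given by chance. A response of BLT2 cells alone adds to the error of this fit, so the fit is not a test of one. The error is also shared with the other steps, where the lines differed more, by at least 1 for 223 genes from 18 h to calcium return. Such an error can hide changes as small as those with 12-HHT, so the 0 is not evidence of no response. Across genes the SD of the 12-HHT difference was 0.134 in Mock and 0.137 in BLT2 cells. For scale, the step from 18 h to calcium return moved 110 genes at least 2-fold in Mock and 301 in BLT2 cells. The 12-HHT differences of the lines differed by at least 1 for 9 genes.

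Across 10498 genes, the changes of Mock and BLT2 cells correlated with Pearson r of 0.726 (Spearman rho 0.657) for 2 h against 0 h and 0.903 (0.884) for 18 h against 0 h. For calcium return against 18 h r was 0.472 (0.415), for calcium return against 0 h 0.570 (0.505), and for 12-HHT against none -0.03 (-0.02). Genes are not independent replicates, and these 5 values describe the arrays only.

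**Figure D2:**
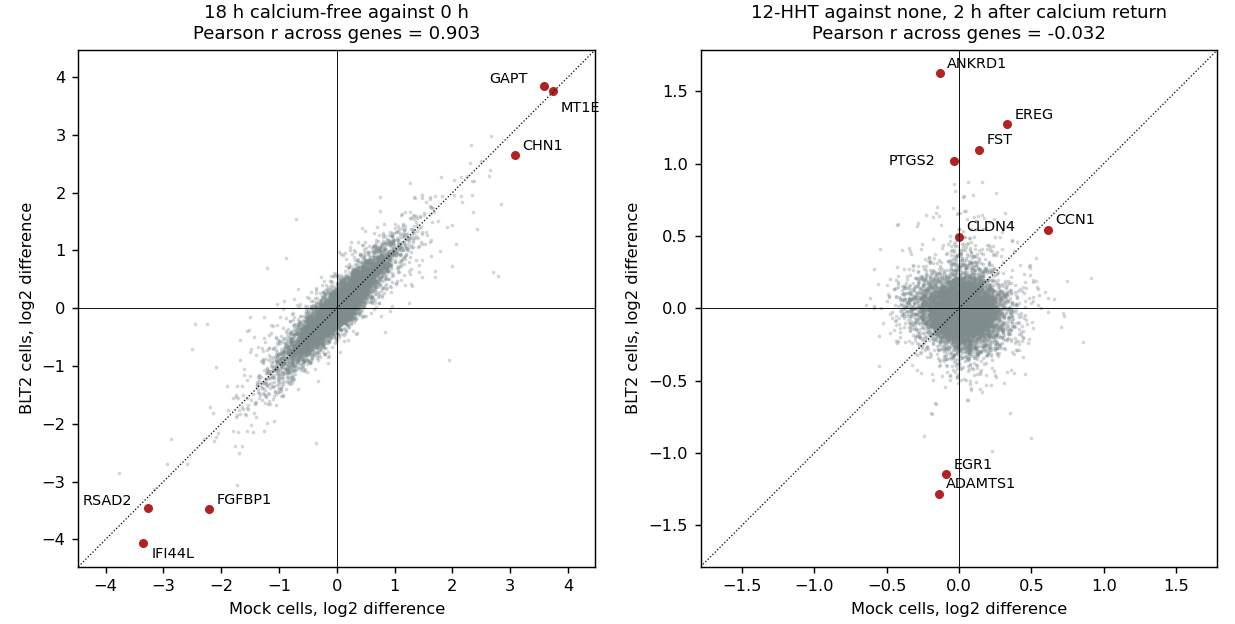
Log2 change in BLT2 cells against that in Mock cells, 1 point per gene, for 18 h against 0 h (left) and 12-HHT against none during calcium return (right), with a dotted line of equal change. The left cloud follows that line (r 0.903), and on the right (r -0.03) ANKRD1 stands at 1.62 in BLT2 and -0.13 in Mock cells. The Mock signals behind the latter value lay below the filter level.

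In the BLT2 line against the Mock line at matched steps, DNM3, a dynamin of membrane fission, was higher by 3.11 ± 0.10 (limma adjusted p = 4.40e-05), IDO1, which degrades tryptophan, by 2.60 ± 0.29, the cytokine gene CSF2 by 2.04 ± 0.35, the lectin gene LGALS1 by 1.92 ± 0.08 and the receptor gene CD40 by 1.91 ± 0.18. Lower were the glutathione transferase MGST1 at -3.67 ± 0.21 (adjusted p = 0.000289), the ubiquitin ligase RNF128 at -2.92 ± 0.16, CYP1A1, an enzyme of xenobiotic metabolism, at -2.69 ± 0.28, the amyloid precursor gene APP at -2.40 ± 0.09 and the glucose transporter SLC2A3 at -2.02 ± 0.16. All 10 genes kept their call without each array. They had the same sign at all 5 steps, which the rule for naming the largest changes required. Among claudins, CLDN16 was lower by a log2 change of -1.83 ± 0.17 (adjusted p = 0.00162), also in every such fit. CLDN2 at -1.40 ± 0.35 (0.0376) lost its call without any 1 of the 2 h, 18 h or 12-HHT arrays (up to 0.0962), and CLDN4 at 0.65 ± 0.15 (0.0265) without any 1 of the 0 h, calcium return or 12-HHT arrays (up to 0.0657). The CLDN2 difference was not level over the steps, since CLDN2 fell far more at 18 h in Mock than in BLT2 cells. Its BLT2 signals at 0 h, 18 h and both calcium return steps lay below the filter level. CLDN1 at -0.35 ± 0.09 (0.0430) was called in none of the 10 fits without 1 array (up to 0.146). CLDN7 at 0.11 ± 0.08 (0.363), OCLN at 0.07 ± 0.09 (0.624), TJP1 at -0.17 ± 0.06 (0.101) and CDH1 at -0.02 ± 0.06 (0.873) did not pass.

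By lists, 19 of 32 DNA replication genes were lower in BLT2 cells, 25 adjusted over the list alone (camera adjusted p = 2.27e-08, and adjusted p = 0.805 with an estimated correlation), among them the primase subunit PRIM1 at -0.74 ± 0.09. Mitosis had 8 of 29 lower and 1 higher, 21 and 2 adjusted over the list alone (adjusted p = 1.83e-06, and adjusted p = 0.805 with an estimated correlation). The ATF4 amino acid response had 11 of 25 lower and 1 higher, 18 and 1 adjusted over the list alone (adjusted p = 1.03e-06, and adjusted p = 0.104 with an estimated correlation), led by VLDLR, a lipoprotein receptor, at -1.37 ± 0.09. Interferon stimulated genes had 8 of 18 higher, 13 adjusted over the list alone (adjusted p = 1.51e-06, and adjusted p = 0.805 with an estimated correlation), among them OAS2 at 1.06 ± 0.19 and MX1 at 0.89 ± 0.13. Integrins and matrix receptors had 10 of 22 higher, 14 adjusted over the list alone (adjusted p = 1.83e-06, and adjusted p = 0.792 with an estimated correlation), among them ITGA6 at 0.86 ± 0.14 and the syndecan SDC4 at 0.65 ± 0.06. NF-kB and inflammation had 6 of 19 higher, 9 adjusted over the list alone (adjusted p = 4.32e-05, and adjusted p = 0.805 with an estimated correlation), among them TNFAIP3, an inhibitor of that pathway, at 1.22 ± 0.20. Cholesterol synthesis had 3 of 19 higher by both counts (adjusted p = 0.00204, and adjusted p = 0.805 with an estimated correlation). Its median BLT2 minus Mock difference was 0.12 at 0 h, 0.15 at 2 h and -0.12 at 18 h, against 0.62 after calcium return and 0.61 with 12-HHT. In the same order of steps the medians were -0.03, -0.38, -0.29, -0.67 and -0.73 for DNA replication, -0.07, -0.21, -0.21, -0.52 and -0.58 for mitosis, and 0.39, 0.34, 0.15, 0.65 and 0.60 for interferon stimulated genes. For NF-kB and inflammation they were 0.28, 0.59, -0.07, 0.43 and 0.53. The epithelial mesenchymal transition list had 5 of 11 higher by both counts (adjusted p = 0.00558, and adjusted p = 0.466 with an estimated correlation), among them the transcription factor SNAI2 at 1.11 ± 0.09 and the matrix protein gene TGFBI at 1.18 ± 0.14. Tight junctions had 2 of 35 higher and 3 lower (adjusted p = 0.600), with a median of 0.07 and a mean of -0.03.

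The lines differed in 1674 of 10498 genes, 821 higher and 853 lower in BLT2 cells, with 69 and 39 of them at least 2-fold. The count was 1114 without either 0 h array, 1116 without either 2 h array, 980 without either 18 h array, 854 without either array of calcium return alone and 575 without either 12-HHT array. Of 90 genes named, 47 stayed called without each array, and 41 lost the call without either 12-HHT array. There was 1 line of each kind, so the receptor and any other difference between the lines cannot be told apart.

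**Figure D3:**
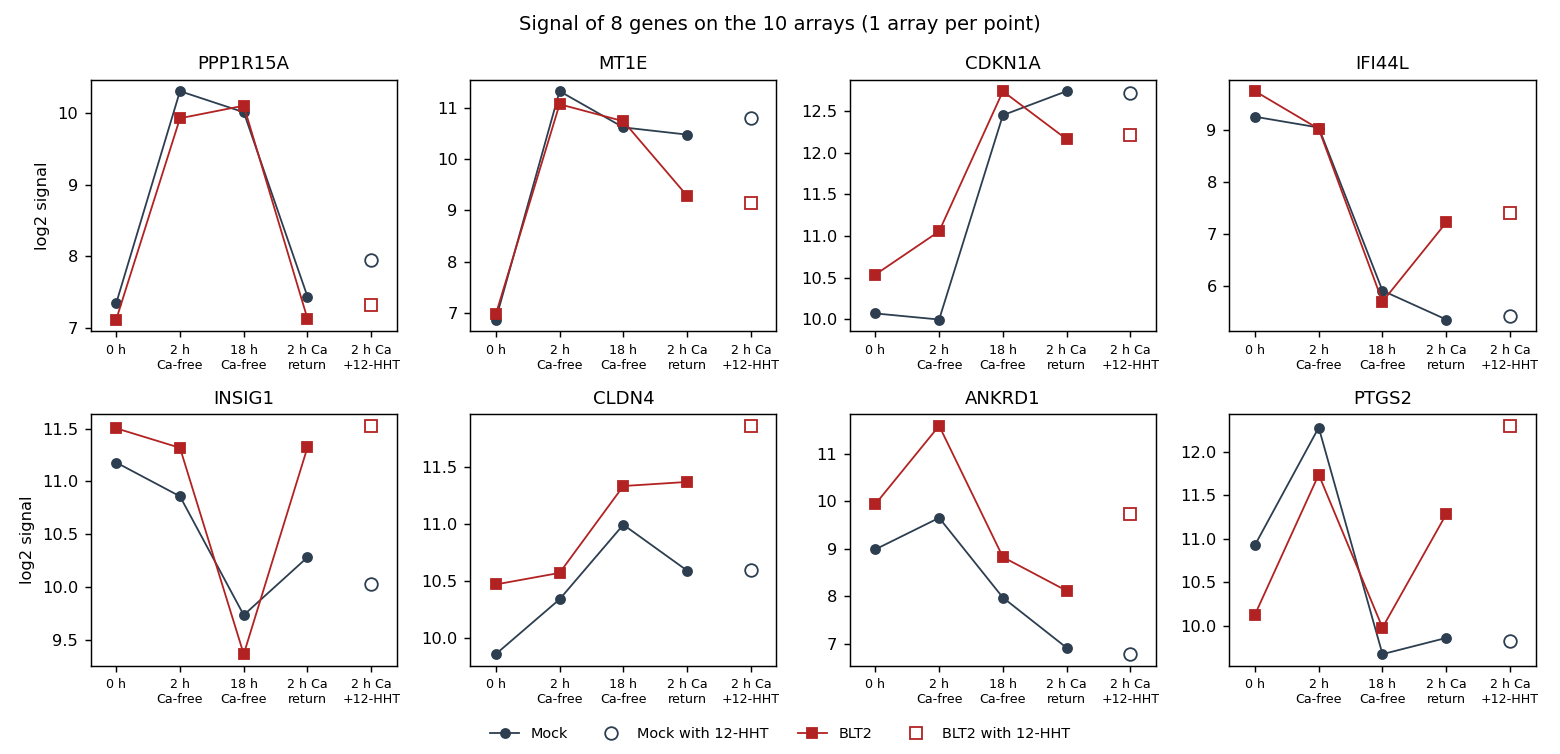
Log2 signal of PPP1R15A, MT1E, CDKN1A, IFI44L, INSIG1, CLDN4, ANKRD1 and PTGS2 on the 10 arrays, by step and line, with open symbols for 12-HHT and 1 array per point. PPP1R15A is up by 2.96 in Mock and 2.81 in BLT2 cells at 2 h, and PTGS2 is at 11.3 without and 12.3 with 12-HHT in BLT2 cells.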

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

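Every test in this part except the splits of the arrays for BLT2 against Mock was chosen only after the result it bears on had been seen, and so was the reading of those splits by step.

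The difference between BLT2 and Mock cells changed with calcium return for 1190 of 10498 genes in limma, tested on the BLT2 minus Mock difference at 2 steps after the return against 3 before it, with 3 residual degrees of freedom. Of these, 892 shifted up in BLT2 relative to Mock cells and 298 down, 160 and 19 of them at least 2-fold, and 3318 had an unadjusted p under 0.05. One of the steps after the return holds 12-HHT, and without its arrays 95 genes were called, all among the 1190, with 2 residual degrees of freedom and 2238 at an unadjusted p under 0.05. The count was 51 without the arrays of calcium return alone, 165 without those at 0 h, 1756 without those at 2 h and 1053 without those at 18 h. IFI44, an interferon stimulated gene, shifted by 2.57 ± 0.12 (adjusted p = 0.000943). It was at -3.16 in Mock and -3.13 in BLT2 cells at 18 h against 0 h, and on calcium return moved by a further -0.59 in Mock and by 1.85 in BLT2 cells. USP18, which limits interferon signalling, shifted by 1.81 ± 0.12 and RSAD2 by 1.91 ± 0.17. MMP13, a collagenase, shifted by 3.08 ± 0.52 (adjusted p = 0.0170) and PTGS2 by 2.29 ± 0.39, but their line differences were not level before the return. BLT2 minus Mock for MMP13 was 0.75 at 0 h, 1.30 at 2 h, 2.65 at 18 h, 4.23 after calcium return and 5.06 with 12-HHT, and for PTGS2 -0.80, -0.54, 0.30, 1.42 and 2.47. COL12A1, a collagen chain, shifted by -2.22 ± 0.15 (adjusted p = 0.00294), HERPUD1, an endoplasmic reticulum stress gene, by -1.75 ± 0.11, MT1E by -1.41 ± 0.18 and CDKN1A by -1.14 ± 0.22. The line difference of CDKN1A was not level before the return either, at 0.47, 1.06, 0.29, -0.58 and -0.50 in the same order of steps. Without the arrays of a step, IFI44, USP18, RSAD2, COL12A1 and HERPUD1 were called in all 5 fits. MMP13 (0.0890), PTGS2 (0.0823), MT1E (0.0537) and CDKN1A (0.1004) lost the call without the 12-HHT arrays, MMP13 (0.0591), PTGS2 (0.0686) and CDKN1A (0.0748) without the 0 h arrays, and MMP13 (0.0661) and CDKN1A (0.136) without those of calcium return alone, values in brackets being adjusted p.

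Among gene lists, interferon stimulated genes shifted up with 7 of 18 called (camera adjusted p = 2.57e-06, and adjusted p = 0.362 with an estimated correlation) and cholesterol synthesis with 11 of 19 (adjusted p = 9.46e-06, and adjusted p = 0.491 with an estimated correlation). Integrins and matrix receptors had 6 of 22 up (adjusted p = 0.00800, and adjusted p = 0.362 with an estimated correlation), and adherens junctions and desmosomes 6 of 23 (adjusted p = 0.0213, and adjusted p = 0.362 with an estimated correlation). Mitosis shifted down with 10 of 29 called (adjusted p = 4.88e-11, and adjusted p = 0.491 with an estimated correlation) and DNA replication with 12 of 32 (adjusted p = 1.17e-10, and adjusted p = 0.491 with an estimated correlation). For p53 targets 7 of 20 shifted down and 1 up (adjusted p = 0.000563, and adjusted p = 0.362 with an estimated correlation), for the unfolded protein response 3 of 22 down (adjusted p = 0.00688, and adjusted p = 0.821 with an estimated correlation). Endothelial markers were lower as a list with 0 of 5 called (adjusted p = 0.0462, and adjusted p = 0.491 with an estimated correlation). The calls of adherens junctions (0.0887) and the unfolded protein response (0.0843) were lost without the 18 h arrays, those of adherens junctions (0.0962) and integrins (0.08845) without the 12-HHT arrays, and that of endothelial markers without the 2 h arrays (0.134) or those of calcium return alone (0.168). Fewer members were called when some steps were left out. Without the 0 h arrays they were 5 for interferon stimulated genes, 3 for cholesterol synthesis, 1 each for DNA replication and the unfolded protein response, and 0 for mitosis, integrins, adherens junctions and p53 targets. Without the arrays of calcium return alone they were 4 for interferon stimulated genes, 1 each for p53 targets and the unfolded protein response, and 0 for cholesterol synthesis, DNA replication, mitosis, integrins and adherens junctions. Without the 12-HHT arrays they were 4 for interferon stimulated genes, 2 for cholesterol synthesis, 1 for the unfolded protein response, and 0 for DNA replication, mitosis, integrins, adherens junctions and p53 targets. Without the 18 h arrays mitosis had 6 lower and p53 targets 4, and without the 2 h arrays the unfolded protein response had 7 lower.

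A fault of the BLT2 array of calcium return without 12-HHT would leave the array with 12-HHT unaffected, but the 221 genes whose return without 12-HHT against 18 h differed at least 2-fold between the lines also differed at the 12-HHT step against 0 h, by a signed median of 0.996, with 215 of the same sign. A signal scale that depends on level is not the whole source either, since after cyclic loess 1492 genes were called, 1128 of them shared. Of the 10 ways to take 2 of 5 steps, only the real one gave as many genes (1190, highest other 1, DPP4, chosen after its values were seen), and 10 ways are too few for a share under 0.05. The other ways mix steps before and after the return, so a true shift enters their error and lowers their counts. A candidate explanation for part of the genes is that the lines recover at different speeds, which these tests leave open. Differences in culture or hybridisation between the lines stay open too, and neither explanation was tested. In BLT2 cells the medians of interferon stimulated genes (-1.09 at 18 h, then 0.46 on return) and cholesterol synthesis (-0.92, then 0.84) moved back. Those of DNA replication (-0.76, then -0.30) and mitosis (-0.50, then -0.34) moved further from 0 h, against 0.06 and -0.05 on return in Mock cells. Different speeds of recovery alone would not give such a further fall, so these values argue against them for those lists.

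With 12-HHT, 6 genes moved at least 2-fold in BLT2 cells and 0 in Mock cells. Over the 47 genes moved at least 1.5-fold in BLT2 cells the median size was 0.669 and the median Mock change in the same direction 0.0573, which is consistent with a response through the added receptor. The 16 genes moved as far in Mock cells, with a median size of 0.631, read -0.0212 in BLT2 cells in the same way, so differences between single dishes may give such a pattern too. A less complete calcium return in the dish with 12-HHT cannot be told apart, since its correlation with the return in Mock cells over the 47 genes was r -0.04997 with an interval of -0.347 to 0.279, and over all genes r was 0.0989. The lists called higher with 12-HHT had negative medians on return against 18 h, -0.27 for immediate early genes, -0.62 for YAP targets and -0.29 for ERK output. CCN1, which fell on return, was higher with 12-HHT in both lines. Both comparisons share the arrays of calcium return alone, so opposite changes can also come from those arrays.

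At 2 h, 103 genes were at least 2-fold lower in BLT2 and 10 in Mock cells. A signal scale that depends on level is not the whole source, as 98 and 8 were past 2-fold after cyclic loess, 86 and 8 of them shared, though the 2 h line difference followed level with r -0.197 across genes. A fault of the BLT2 2 h array alone would leave Mock cells near 0, but 101 of these genes measured in Mock cells had a median of -0.498 there, outside the -0.0548 to 0.0437 of random lists, with 99 below 0. The mean correlation of that array with the others was 0.975, and 0.976 after cyclic loess, where the lowest of the others was 0.982, and over probe sets without a symbol it was 0.9685 against 0.98. Lower RNA quality on that array, which could raise the size of the changes, and a stronger response of the BLT2 line were not tested.

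For BLT2 against Mock, of 100 splits drawn from 126 only the real one itself reached its 1674 genes, with 1223 as the highest of the others. That number came from 2 splits, which part 3 steps and follow the lines in all 3. Because the fit holds the step as a term, a split that keeps both arrays of a step together removes that step from the estimated difference. The line difference at that step then enters the error, so such a split cannot rank the real one. The splits that part every step number 16, too few for a share under 0.05, and of the 13 of them drawn the highest other than the real one was 0 genes. The others reverse the line labels at some steps, so a true line difference enters their error and a low count is built in.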

How the results depend on the processing

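Cyclic loess, the list tests without each array (added lists included) and the return test without each step were chosen only after the data were seen, and the other alternatives were planned. No named gene that was called changed direction under any alternative in which it was tested. Named genes without a call in a fitted comparison were not followed in this way. Over pairs of named gene and setting, the call was kept in 2987 and lost in 257 in settings other than leaving out 1 array, and kept in 2626 and lost in 1024 with 1 array left out. Array number limits precision, low signals lie near background, and no group had 2 arrays, so a fit without 1 array takes the spread of the other steps for the step left with 1. Replicates could not be paired because each combination has 1 array and so no second replicate number. The additive fit is itself paired in another way, as it compares steps within each line and lines within each step.

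For 2 h against 0 h, 485 genes became 309 with no signal filter, 312 with median centring (211 higher and 101 lower, or 67.6% higher against 57.1%), 1805 with 4 arrays only (777 higher and 1028 lower), 298 without the 12-HHT arrays, and 34 (without the BLT2 0 h array) to 1024 (without the Mock 2 h array) with 1 array left out. For 18 h, 2860 became 5460 with 4 arrays only and 591 to 3148 with 1 array left out, lowest without the BLT2 18 h and highest without a 2 h array. For calcium return against 18 h, 351 became 230 with no filter, 168 with 4 arrays only, 228 without the 12-HHT arrays and 2 (without the BLT2 18 h array) to 375. Against 0 h, 1579 became 643 with 4 arrays only and 40 (without the BLT2 0 h array) to 1848. For BLT2 against Mock, 1674 became 386 without the step term, 575 without the 12-HHT arrays and 575 to 1116 with 1 array left out. For 12-HHT the count stayed 0 in limma in all settings, with 17 to 392 at an unadjusted p under 0.05. The 392 came with 4 arrays only. All other settings share the error of the other steps, so they are not independent checks of the 0. After cyclic loess the counts were 570, 2986, 410, 1682, 0 and 1698. The 1190 genes of the difference between lines on calcium return became 1492 after cyclic loess and 51 to 1756 with 1 step left out. Quantile normalization, median centring and cyclic loess moved the median of all genes by at most 0.0450.

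With an estimated correlation the lists called fell from 12 to 3 at 2 h, and to 0 from 11 at 18 h, 12 for return against 18 h, 12 for return against 0 h, 3 for 12-HHT and 8 for BLT2 against Mock. With 1 array left out they ranged from 7 (without the Mock 2 h array) to 12 at 2 h and from 3 to 13 (without the Mock 12-HHT array) for 12-HHT. DNA replication at 2 h had an adjusted p of 4.34e-08 to 0.666 with 1 array left out, and its direction was reversed at the latter, without the BLT2 0 h array. The cause was not tested.

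For 12-HHT by line, Mock had 2 genes with no filter (OR52U1C and LOC484858, chosen after their values were seen) and 11 at 1.5-fold, against 0. BLT2 had 48 at 1.5-fold, against 6. The 11 and 48 are counted among genes whose higher signal of the pair lay above 7.21, and the 16 and 47 given earlier among the 10498 tested genes. Between lines, 9 became 32 with no filter, 5 with the stricter filter (ANKRD1, EGR1, OSR1, PTGS2 and VASN) and 109 at 1.5-fold. The r between lines became 0.5797 at 2 h and 0.365 for return against 18 h with no filter, and 0.0718 for 12-HHT with the stricter filter.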

Other observations

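The 3 gene lists in this part and their tests were chosen only after the data had been seen, so their tests are not independent evidence.

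Targets of the aryl hydrocarbon receptor, a sensor of xenobiotics, were higher at 2 h, with 4 of 5 tested genes called (camera adjusted p = 4.42e-07, and adjusted p = 0.0356 with an estimated correlation). CYP1A1 rose by 3.13 ± 0.45 (limma adjusted p = 0.0144), TIPARP by 2.09 ± 0.13, CYP1B1 by 1.61 ± 0.11 and NFE2L2 by 0.57 ± 0.09. CYP1A1 was not called without the BLT2 2 h array (adjusted p of 0.0568), nor NFE2L2 without the Mock 0 h, BLT2 0 h or BLT2 2 h array (up to 0.189). At 18 h CYP1B1 and TIPARP were lower, at -0.50 ± 0.11 and -0.48 ± 0.13, and the list was not called (camera adjusted p = 0.946). Neither gene was called there without any 1 of the 0 h and 18 h arrays. TIPARP was at -0.31 without the Mock 0 h and -0.65 without the BLT2 0 h array. Both rose again on calcium return against 18 h, CYP1B1 by 0.66 ± 0.11 and TIPARP by 1.25 ± 0.13 (list adjusted p = 0.0981). TIPARP was not called there without the Mock 18 h, BLT2 18 h or Mock calcium return array (adjusted p of up to 0.1301), and CYP1B1 without any 1 of the 0 h, 18 h or calcium return arrays (up to 0.316). After calcium return against 0 h the list was higher with 2 of 5 called (camera adjusted p = 0.0496, and adjusted p = 0.420 with an estimated correlation). These were CYP1A1 at 2.13 ± 0.45 and TIPARP at 0.77 ± 0.13. CYP1A1 lost the call without the Mock 0 h or either calcium return array, TIPARP without the BLT2 0 h or BLT2 calcium return array, and the list in most fits without 1 array. Medium was changed 2 h before harvest at the 2 h and calcium return steps, and 18 h before it at the 18 h step.

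Replication-dependent histone genes were lower at 18 h with 11 of 13 called (camera adjusted p = 7.93e-09, and adjusted p = 0.293 with an estimated correlation), and after calcium return against 0 h with 12 of 13 (adjusted p = 3.14e-14, and adjusted p = 0.200 with an estimated correlation). At 2 h they were higher with 2 of 13 called (adjusted p = 3.40e-05, and adjusted p = 0.317 with an estimated correlation), and calcium return against 18 h had 2 of 13 lower (adjusted p = 0.00114, and adjusted p = 0.404 with an estimated correlation). In BLT2 against Mock cells 4 of 13 were lower (adjusted p = 0.00451, and adjusted p = 0.642 with an estimated correlation). The 2 genes called at 2 h (H2AC13 and H2AC6) were not called without the Mock 0 h, BLT2 0 h or BLT2 2 h array, nor the 2 on calcium return (H2AC20 and H2BC1) without any 1 of the 4 arrays of those steps, and the 4 in BLT2 against Mock cells became 2 without either 2 h, calcium return or 12-HHT array. H2BC11 fell by 3.31 ± 0.27 at 18 h and H1-1 by 2.11 ± 0.10. Probes of near-identical histone genes can share targets, so single members are uncertain. Class II genes of the major histocompatibility complex, which present antigen, were higher at 18 h with 4 of 6 called (adjusted p = 0.00485, and adjusted p = 0.560 with an estimated correlation), among them DLA-DQA1 at 2.15 ± 0.30 and DLA-DRA at 1.45 ± 0.29. After calcium return 4 of 6 were higher against 0 h (adjusted p = 0.000389, and adjusted p = 0.420 with an estimated correlation), and 4 of 6 were lower in BLT2 than in Mock cells (adjusted p = 0.0106, and adjusted p = 0.642 with an estimated correlation). Of the 4 called at 18 h, 2 stayed called without the Mock 0 h or Mock 18 h array and 1 without the BLT2 0 h array, and DLA-DRA was lost without the Mock 18 h or BLT2 0 h array (up to 0.0865). Of the 4 called after calcium return, 2 stayed called without the Mock 0 h or BLT2 calcium return array and 0 without the BLT2 0 h array. Of the 4 lower in BLT2 cells, 2 stayed called without either 0 h, 2 h or 12-HHT array and 1 without either 18 h array.

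Probe sets not listed with a gene symbol also moved. When all 17509 probe sets past the signal filter were tested, 6498 were not listed with a symbol, and limma called 265 of them at 2 h, 716 at 18 h, 67 for return against 18 h, 222 for return against 0 h and 228 for BLT2 against Mock. For 12-HHT it called 0 of these, and 0 of all 17509 with 87 at an unadjusted p under 0.05.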
